A study of Mus musculus with 12 samples.

How the data were processed

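Gene expression was measured by RNA sequencing in retinal pigment epithelium (RPE) of mice with a conditional deletion of Sox9 (cKO) and of wild-type (WT) mice, at embryonic day 15.5 (E15.5) and postnatal day 5 (P5), with 3 libraries in each of 4 groups. The column titles, which carry age, genotype (wt or kd) and replicate number, assigned the 12 libraries to their groups. Libraries titled kd are called cKO here. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.10 to the mm10 genome and counted with HTSeq. The deposited table holds 1 signal value per gene and library: gene counts that the authors quantile-normalised across the libraries, with values under 50 set to 50, as its name states. The values were checked against this: all 12 columns held the same sorted values, the lowest was 50 and 1376 values, or 9.87% of each column, lay at that floor. The annotation release, the strand setting, the gene filter before this table and the sequencing depth are not given in the sources used here. The deleted exons of Sox9, the Cre line and the way RPE was separated are likewise not given there. Because each library was forced onto 1 distribution, the column sum of 12618429 is the same for all and says nothing about depth, so no counting error could be attached to a value.

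The table held 13942 genes by Ensembl identifier and symbol, of which 13927 were found in GENCODE release M21 (GRCm38), the source of the positions printed. Genes above the floor in at least 3 of the 12 libraries were tested, 13523 in all. The values were taken as log2(value + 1), and a linear model with 1 mean per group over all 12 libraries was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes with a mean-variance trend). All limma tests were two-sided. P-values were adjusted over the genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p in the text comes from limma's test of single genes unless it is said to come from camera or fry. The contrasts were cKO minus WT at each age, P5 minus E15.5 in each genotype, and their interaction. Log2 fold changes come with the standard error (SE) of the model, group values as mean and SD of 3 libraries on the scale of the table. For single genes an exact permutation test of 3 libraries against 3 was added, two-sided, whose smallest possible p is 0.1. A gene at the floor in all libraries of a group has a fold change that is a lower bound. The labels do not say whether the replicates of a group were separate animals, so the p-values measure only the spread between samples.

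Gene lists, the rule for named genes, the model and most of its alternatives were fixed before the data were examined. The 30 lists covered the functions of RPE (melanin synthesis and melanosome; visual cycle and retinoid handling; RPE transcription factors; RPE transport, phagocytosis and polarity), SOX9 and signalling (Sox family other than Sox9, SOX9-dependent cartilage genes, angiogenic and angiostatic secreted factors, Wnt, TGF-beta and BMP, basement membrane and elastic matrix), cell state (cell cycle, cyclin-dependent kinase inhibitors and p53 targets, lysosome, cholesterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, interferon response, immediate early and heat shock genes) and other tissues (retinal progenitors, retinal neurons, photoreceptors, glia, endothelium, pericytes with smooth muscle and mesenchyme, neural crest melanocytes, macrophages and microglia, erythroid cells, lens, skeletal muscle, ciliary body and iris). Each list was tested with limma's camera, which compares its genes with all others, at the preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists of a contrast. No list was called with an estimated correlation in any of the 5 contrasts. The estimates lay between -0.03 and 0.95, at 0.76 for lens and 0.89 for skeletal muscle markers. A call at the preset is weak evidence where the estimate is high. Another list test of limma, fry, called no list for genotype (lowest adjusted p by fry 0.998 at E15.5 and 0.12 at P5). Calls within a list are given over all genes and adjusted over the list alone.

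The named genes were Sox9, the 10 largest called rises and 10 largest called falls per genotype comparison whose libraries did not overlap, up to 4 members per list (called members first, then by size of change), the 8 largest rises and falls per age comparison and the 5 largest interactions in each direction. Predicted genes without an established name were passed over. Of the list members that the rule names the text prints a part, chosen after their values were seen, and the counts per list cover the others. Apart from these, 1 gene that the rule names is not reported here.

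The model was tested on simulated data with the floor of the table and a spread per gene pooled over the 4 groups. In these, 100 genes were changed 2-fold and 100 genes 4-fold, all averaging over 4 times the floor. The model called 61% and 89% of these at E15.5, 70% and 89% at P5, 65% and 88% for age in WT and 35% and 73% for the interaction, and 6.09% to 11.7% of all calls were false. Noise was drawn independently for each value, so the simulation held neither the larger spread at P5 nor signal shared between libraries. The shares describe that setting and may not hold for the deposited values. Alternatives covered the pseudocount, the filter, rescaling of the libraries by median ratios, the variance model, library weights, a fit of only the 6 libraries compared, leaving out each replicate, the replicate number as a block, and, chosen after the data were seen, terms for photoreceptor, lens, melanosome and muscle signal and the omission of a pair of P5 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Read-level data, exon use and splice forms were not analysed here.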

Results

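RNA was profiled in mouse RPE, the pigmented layer behind the retina, in 3 libraries each of WT at E15.5, cKO at E15.5, WT at P5 and cKO at P5. SOX9 is a transcription factor of the RPE, and the design asks which genes differ without it before birth and after. Values are quantile-normalised gene counts with a floor of 50 and a median of 367.4 in every library, and the sequencing depth behind them is unknown. Within groups, the correlation between libraries across genes was 0.990 to 0.993 in E15.5 WT and 0.985 to 0.988 in E15.5 cKO, but 0.840 to 0.966 in P5 WT and 0.910 to 0.977 in P5 cKO. The median SD between replicates on the log2 scale was 0.105 and 0.116 at E15.5 against 0.317 in WT and 0.232 in cKO at P5. The first principal component, 65.4% of the variance, separated the ages, and the second, 19.999%, spread the P5 libraries. Markers of other tissues varied between the P5 libraries. The mean log2 value of the photoreceptor list was 7.10, 8.18 and 10.96 in the WT libraries and 7.09, 10.1 and 9.18 in the cKO libraries at P5, against 5.98 to 6.04 at E15.5.

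**Figure D1:**
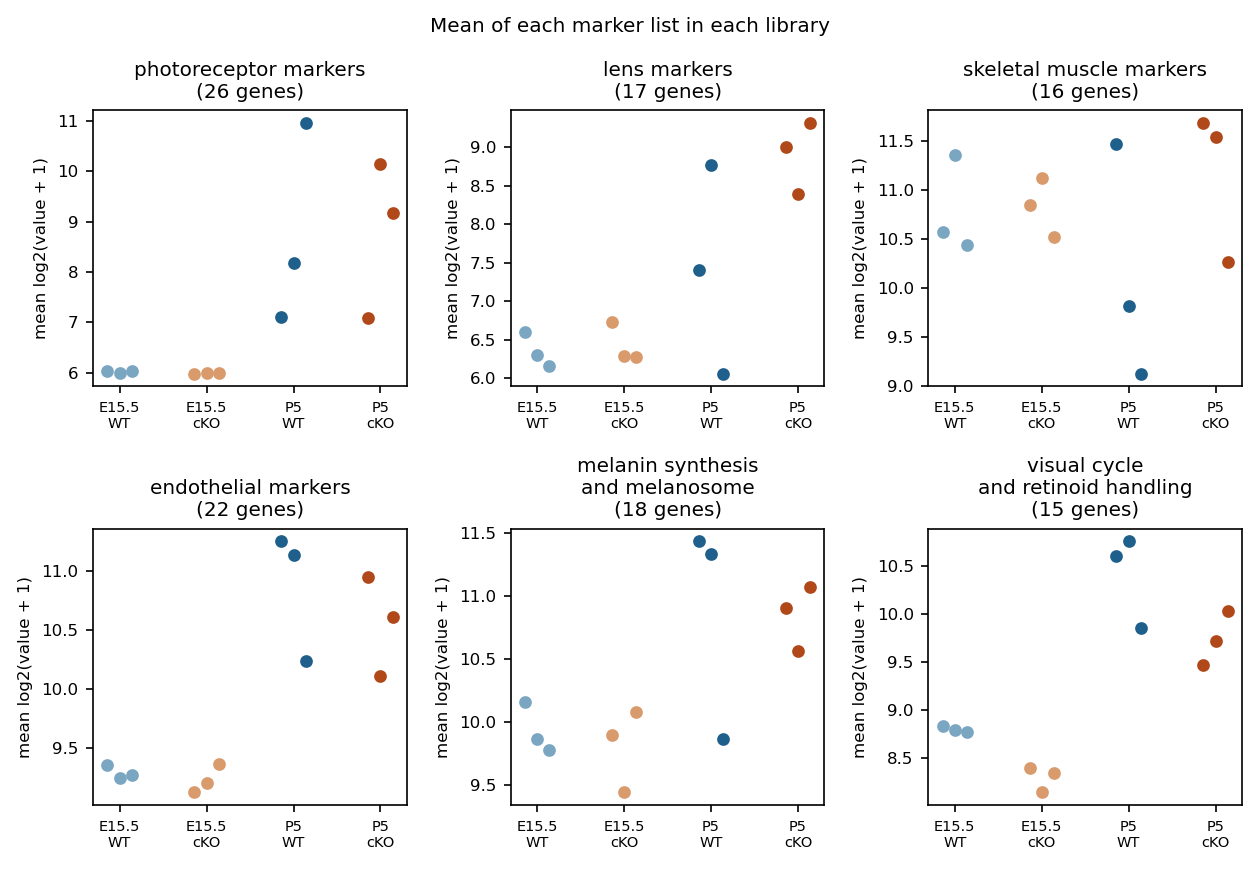
Mean log2(value + 1) of 6 gene lists (vertical axes) in each of the 12 libraries (points) by group (horizontal axes). Photoreceptor signal spread from 7.09 to 10.96 among the P5 libraries of both genotypes, while lens signal was 8.39 to 9.31 in P5 cKO and 6.06 to 8.76 in P5 WT.

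The gene count of Sox9 itself was not called lower in the libraries labelled cKO at either age. Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760, GRCm38) stood at 1049 ± 113 (SD, n = 3) in WT and 1010 ± 22.3 (SD, n = 3) in cKO at E15.5, a log2 fold change of -0.05 ± 0.17 (SE) with an exact permutation p of 0.7. At P5 it rose from 1192 ± 277 (SD, n = 3) in WT to 2482 ± 405 (SD, n = 3) in cKO, a log2 fold change of 1.07 ± 0.17 (SE) with an adjusted p of 0.0316 by limma. That direction is opposite to the label. All 3 cKO libraries (2136, 2384 and 2928) lay above all 3 WT libraries (964, 1500 and 1111), which gives the smallest exact permutation p possible, 0.1. A gene count adds up all exons of the gene, and the exons deleted are not given in the sources used here. The call at P5 was lost in a fit of the 6 P5 libraries alone (the same log2 fold change with an SE of 0.21, adjusted p = 1, in a range of 0.00871 to 1 over all alternatives), with a term for lens signal (log2 fold change 0.80, adjusted p = 0.171), with library weights (0.68, adjusted p = 0.236) and among genes averaging at least 4 times the floor (adjusted p = 0.0848). It was also lost without P5 WT replicate 1 (0.93, adjusted p = 0.0599), cKO replicate 2 (1.09, adjusted p = 0.149) or cKO replicate 3 (0.95, adjusted p = 0.151). The replicate number as a block ended the call too (1.07, adjusted p = 0.11).

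**Figure D2:**
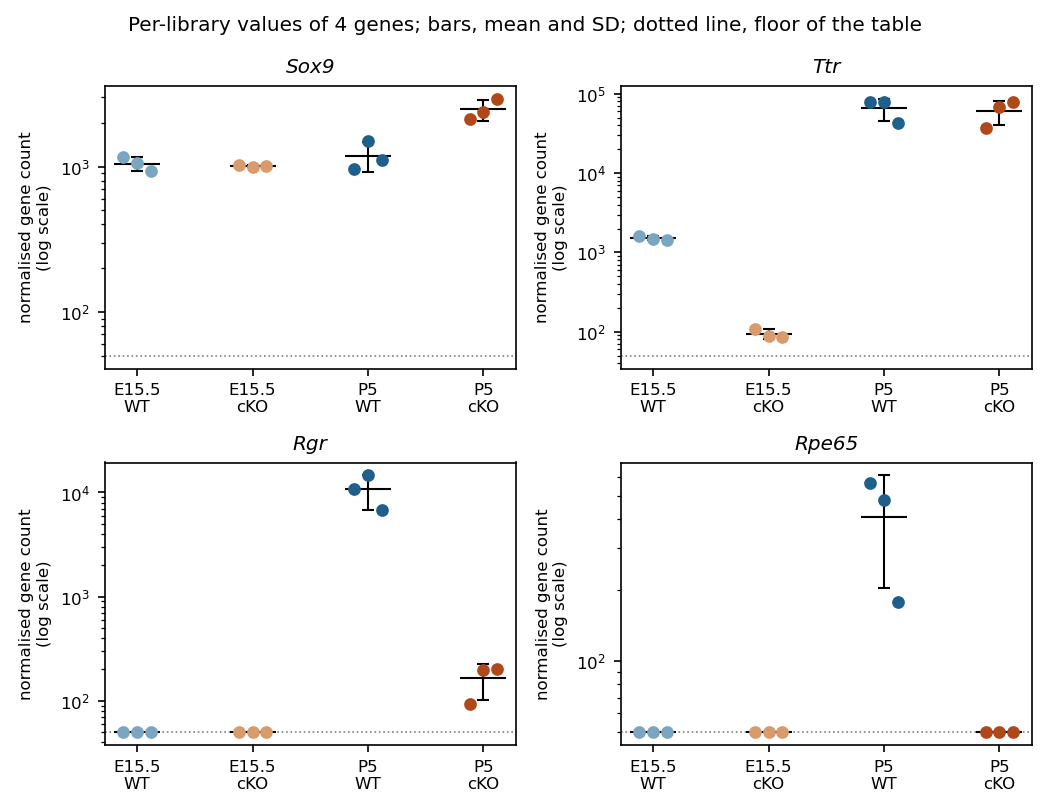
Values of Sox9, Ttr, Rgr and Rpe65 (vertical axes, normalised gene count, log scale) in the 12 libraries by group, with the mean and SD of each group (black bars) and the floor of 50 (dotted line). Ttr was lower in cKO at E15.5, Rgr and Rpe65 were lower in cKO at P5, and Sox9 was higher in cKO at P5.

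At E15.5, 1 gene separated the genotypes: transthyretin (Ttr), the carrier of thyroid hormone and of retinol-binding protein. Ttr (ENSMUSG00000061808, chromosome 18, 20665280 to 20674321) fell from 1510 ± 80.7 (SD, n = 3) in WT to 94.8 ± 13.2 (SD, n = 3) in cKO, 15.9-fold, with a log2 fold change of -3.99 ± 0.29 (SE) and an adjusted p of 0.000521 by limma. All 3 cKO libraries lay below all 3 WT libraries, with an exact permutation p of 0.1. The next largest value among RPE genes was that of Slc16a8, the lactate transporter MCT3 of the RPE, at 269 ± 52.2 (SD, n = 3) in WT and 56.7 ± 5.84 (SD, n = 3) in cKO. Its log2 fold change of -2.21 ± 0.36 (SE) did not pass over all genes (adjusted p = 0.498).

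Of the 15 genes tested for the visual cycle and retinoid handling, 1 fell over all genes and 2 fell adjusted over the list alone, Ttr and the retinol dehydrogenase Rdh10 (1450 ± 276 in WT and 595 ± 49.1 in cKO, SD, n = 3). Rdh5, which makes 11-cis retinal, had a log2 fold change of -0.74 ± 0.38 (SE) and the retinal carrier Rlbp1 (CRALBP) one of -0.61 ± 0.20 (SE), neither of which passed. The list was called lower in cKO (median log2 fold change -0.13, adjusted p = 1.7e-11 by camera), with an adjusted p = 0.313 with an estimated correlation. Of the 16 retinal progenitor markers, none passed over all genes and 3 fell adjusted over the list alone: Fgf15, Atoh7 and Foxn4. Foxn4 had a log2 fold change of -1.10 ± 0.24 (SE), and the progenitor regulators Six6 and Neurog2 had values of -1.25 ± 0.90 and -1.25 ± 0.51 (SE) that did not pass. This list was called lower (median -0.33, adjusted p = 4.44e-13 by camera), with an adjusted p = 0.181 with an estimated correlation. Among the 29 RPE transport, phagocytosis and polarity genes, Slc16a8 alone fell adjusted over the list alone. No member of any other list passed either way, including the 18 melanosome genes (median -0.09, adjusted p = 0.32 by camera), the 13 RPE transcription factors, the 16 SOX9-dependent cartilage genes and the 34 cell cycle genes. Values such as Dct at -0.28 ± 0.30, Otx2 at -0.19 ± 0.45, Col9a3 at -1.07 ± 0.31 and Ccnd1 at -0.37 ± 0.23 (log2 fold change and SE) are given without a call.

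The limma fit counted 0 rises and 1 fall at E15.5, and 49 of 13523 genes had an unadjusted p under 0.05, where 676 would be expected by chance. That fit pools the spread with the more variable P5 libraries: in the 6 E15.5 libraries alone 371 genes had an unadjusted p under 0.05, and with library weights 782. The groups did not overlap in 5.10% of the genes tested, against 10% by chance. Library weights raised the count of calls to 14, and leaving out E15.5 cKO replicate 3 raised it to 4. With the replicate number as a block no gene was called, Ttr included.

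At P5, a retinal opsin and a visual cycle enzyme led the falls. Rgr (ENSMUSG00000021804, chromosome 14, 37034909 to 37048964), an opsin of the RPE and Müller glia that photoisomerises retinal, fell 65.0-fold from 10696 ± 3907 (SD, n = 3) in WT to 165 ± 62.5 (SD, n = 3) in cKO, a log2 fold change of -6.02 ± 0.32 (SE) with an adjusted p of 1.91e-05 by limma. Rpe65 (ENSMUSG00000028174, chromosome 3, 159599175 to 159625321), the retinoid isomerohydrolase of the visual cycle, was at 407 ± 203 (SD, n = 3) in WT and at the floor in all 3 cKO libraries, at least 7.15-fold lower (log2 fold change -2.84 ± 0.33, SE, adjusted p = 0.00617 by limma). The other falls were Chadl, a chondroadherin-like matrix protein (-1.43), the potassium channel Kcna2 (-1.11), Lgi4, a secreted factor of peripheral myelination (-1.01, at the floor in all cKO libraries), and the membrane-type metalloproteinase Mmp17 (-0.90). Ttr did not pass at P5, at 65674 ± 20396 in WT and 60978 ± 21046 in cKO (SD, n = 3, log2 fold change -0.12 ± 0.29, SE). In 3 of the 6 P5 libraries Ttr held the same value, 77449.3, that of a rank shared through quantile normalisation, which limits what can be seen of a difference at that age.

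The 10 largest rises at P5 had log2 fold changes from 1.81 to 2.62. Vstm2a rose from 66.8 ± 29.0 (SD, n = 3) to 404 ± 115 (SD, n = 3), and Nap1l5, an imprinted gene, from 238 ± 43.7 to 1162 ± 515 (SD, n = 3). The potassium channel Kcnh1 (2.15 ± 0.18, SE), the muscarinic acetylcholine receptor Chrm1 (2.14 ± 0.32, SE), the neuronal calcium-binding protein Necab2 (2.09 ± 0.32, SE) and the potassium channel subunit Kcnip4 (1.89 ± 0.30, SE) rose too. So did Ism2 (2.05 ± 0.14, SE), Otogl (2.04 ± 0.18, SE) and the Foxo1 corepressor Fcor (1.81 ± 0.27, SE). Lypd1, a modulator of nicotinic receptors, was at the floor in all 3 WT libraries and at 183 ± 18.1 (SD, n = 3) in cKO, at least 3.59-fold higher. Of the 27 genes that rose, 4 were at the floor in all P5 WT libraries.

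**Figure D3:**
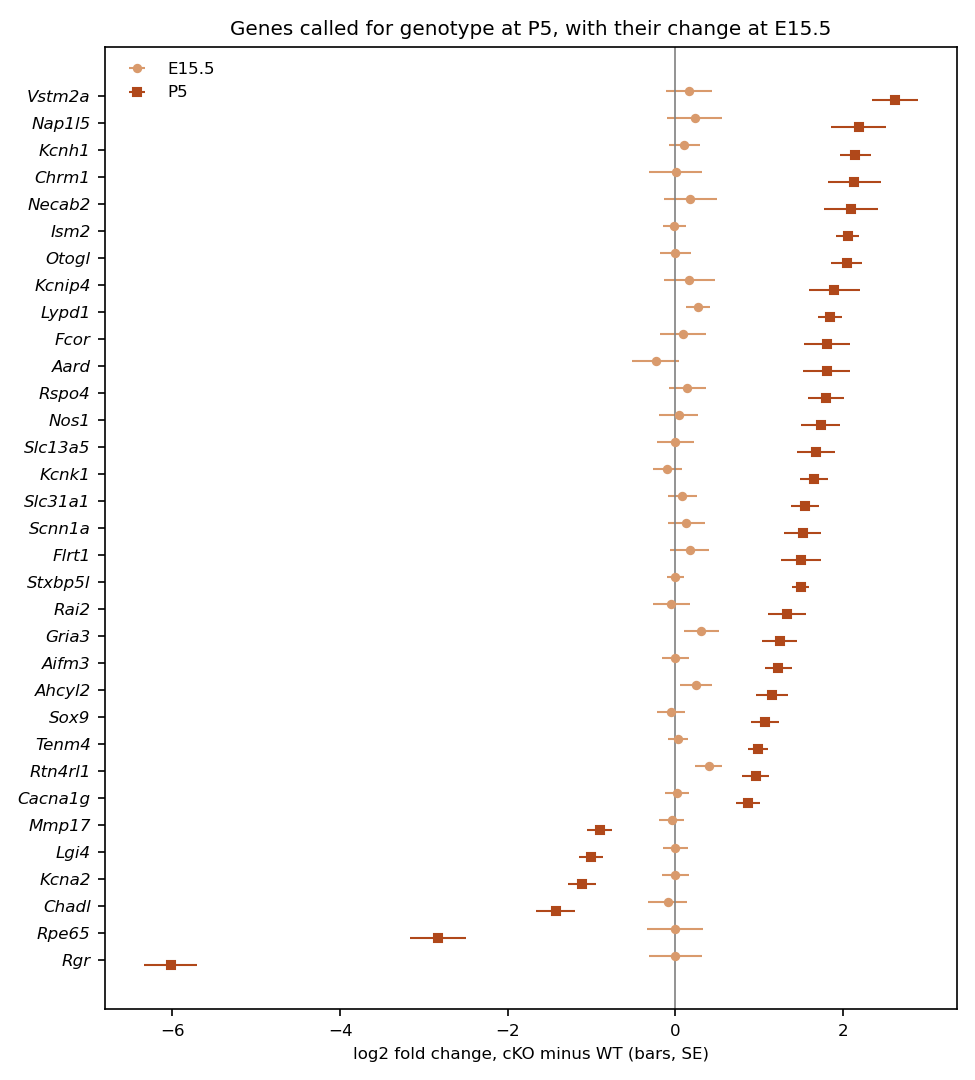
Log2 fold change, cKO minus WT, with SE (horizontal axis) of the 33 genes called at P5 (vertical axis), at P5 (squares) and at E15.5 (circles). At P5 27 lay above 0 and 6 below, led by Rgr at -6.02 and Vstm2a at 2.62, and none of them was called at E15.5.

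Among the RPE lists at P5, 2 of 15 visual cycle genes fell over all genes and 3 adjusted over the list alone, with Rlbp1 at -0.72 ± 0.20 (SE). Ttr, Rdh5 and Rdh10 did not pass. The list was called lower (median -0.18, adjusted p = 0.00861 by camera), with an adjusted p = 0.666 with an estimated correlation. Of 13 RPE transcription factors, Sox9 alone rose, over all genes and adjusted over the list alone, beside Lhx2 at 0.84 ± 0.30 (SE), which did not pass. This list was called higher (median 0.30, adjusted p = 0.00103 by camera), with an adjusted p = 0.392 with an estimated correlation. None of the 29 RPE transport, phagocytosis and polarity genes passed over all genes. Adjusted over the list alone, 2 rose, Slc9a3r1 (1.77 ± 0.34, SE) and the sodium pump subunit Atp1b1 (1.18 ± 0.30, SE), and 1 fell, the amino acid transporter Slc6a20a (-2.20 ± 0.49, SE). The transport list was called higher (median 0.44, adjusted p = 0.000931 by camera), with an adjusted p = 0.666 with an estimated correlation. No melanosome gene passed, and that list was not called (18 genes, median -0.08, adjusted p = 0.978 by camera). Without P5 WT replicate 3, the library of highest photoreceptor signal, the transcription factor (median 0.15) and transport (median 0.10) lists were no longer called and the visual cycle list had a median of -0.40.

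Of the lists tied to SOX9 and signalling, no member passed over all genes at P5. Of 16 SOX9-dependent cartilage genes, 4 fell adjusted over the list alone, Col9a1 (-1.40 ± 0.39, SE), Col9a2 (-0.97 ± 0.26, SE) and Sox5 (-0.83 ± 0.19, SE) among them, and the list was called lower (median -0.26, adjusted p = 0.00235 by camera), with an adjusted p = 0.392 with an estimated correlation. The 14 other Sox genes were called lower (median -0.24, adjusted p = 0.00776 by camera), Sox5 alone falling adjusted over the list alone, with an adjusted p = 0.358 with an estimated correlation. Of these 14 genes, 6 stand in another list too, among them the cartilage, endothelial and neural crest melanocyte lists, which were also called lower. Of 27 TGF-beta and BMP genes, 6 rose adjusted over the list alone, among them Bmp6 (1.31 ± 0.38, SE), Id1 (1.23 ± 0.36, SE) and Bmp2 (1.06 ± 0.35, SE), and the list was called higher (median 0.16, adjusted p = 0.00861 by camera), with an adjusted p = 0.666 with an estimated correlation. The 21 cholesterol synthesis genes were called lower (median -0.19, adjusted p = 0.000193 by camera) with 2 falling adjusted over the list alone, Idi1 and Cyp51, and an adjusted p = 0.392 with an estimated correlation. The 27 oxidative phosphorylation genes were called higher (median 0.11, adjusted p = 0.00267 by camera) with no member passing, and an adjusted p = 0.666 with an estimated correlation. Among 15 cyclin-dependent kinase inhibitors and p53 targets, Sesn2 and Ccng1 rose adjusted over the list alone, and the list was not called. Without P5 WT replicate 3, the other Sox genes (median -0.32) and the TGF-beta and BMP list (median 0.01) were no longer called, and the medians were -0.47 for the cartilage genes and -0.36 for cholesterol synthesis.

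Of the lists of other tissues, 4 were called for genotype at P5 at the preset correlation. The lens list was called higher in cKO (17 genes, median 1.86, adjusted p = 3.51e-10 by camera), with an adjusted p = 0.392 with an estimated correlation. No lens gene passed over all genes and 11 rose adjusted over the list alone, such as the crystallins Crybb1 (328 ± 346 in WT and 1075 ± 343 in cKO, SD, n = 3) and Cryaa (1140 ± 1098 and 3149 ± 1060, SD, n = 3). The skeletal muscle list was called higher (16 genes, median 0.99, adjusted p = 8.55e-07 by camera) with no member passing, and an adjusted p = 0.606 with an estimated correlation. Endothelial markers were called lower (22 genes, median -0.30, adjusted p = 0.000766 by camera), with Kdr at -0.78 ± 0.22 (SE), no member passing, and an adjusted p = 0.666 with an estimated correlation. Neural crest melanocyte markers were called lower (10 genes, median -0.21, adjusted p = 0.0335 by camera), Ednrb falling adjusted over the list alone, with an adjusted p = 0.392 with an estimated correlation. Glial markers were not called, though Gfap, S100b and Cnp fell and Apoe rose adjusted over the list alone. The photoreceptor list was not called and no member passed (25 genes, median 0.12, adjusted p = 0.97 by camera). In the other 14 lists, among them Wnt, angiogenic factors, cell cycle and macrophage markers, no member passed either way and none was called. Without P5 WT replicate 3 the medians were 1.08 for lens, 0.49 for skeletal muscle, -0.66 for endothelium and -0.35 for melanocytes, and these lists were still called at the preset.

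The limma fit at P5 called 27 rises and 6 falls, 24 and 5 of them at least 2-fold. In that fit 1039 genes had an unadjusted p under 0.05 and in the 6 P5 libraries alone 388, where 676 would be expected by chance. The balance of rises and falls was 14 and 27 with a term for lens signal, 27 and 32 with library weights and 38 and 40 without WT replicate 3. In all 33 the libraries of the groups did not overlap, which 6.18% of the tested genes showed, against 10% by chance. A fit of the 6 P5 libraries alone left every log2 fold change as it was, with fewer degrees of freedom (5.21 instead of 10.6), and kept 2 of the 33 calls. There Rgr stood at -6.02 ± 0.43 (SE) with an adjusted p of 0.102 (2.01e-07 to 0.102 over its alternatives) and Rpe65 at -2.84 ± 0.46 (SE) with one of 0.918 (9.01e-07 to 0.918). A term for lens signal kept 13, library weights kept 20 of 33 among 59 calls, the filters kept 19 (above the floor in at least 6 libraries) and 4 (at least 4 times the floor on average), and terms for photoreceptor and melanosome signal gave 206 and 225 calls that held all 33, while a term for muscle signal gave 26 that held 21. Leaving out 1 library gave 78 calls without WT replicate 3, 132 without cKO replicate 1, 14 without cKO replicate 2 and 12 without cKO replicate 3, and leaving out the pair of lowest photoreceptor signal gave 100.

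Between E15.5 and P5, the largest rises in WT included the RPE genes Rgr and Ttr, and 34 of 34 cell cycle genes fell. Rgr was at the floor in all 3 E15.5 WT libraries and at least 200-fold higher at P5, with a log2 fold change of 7.64 ± 0.32 (SE) and an adjusted p of 4.32e-07 by limma. Ttr rose from 1510 ± 80.7 to 65674 ± 20396 (SD, n = 3), a log2 fold change of 5.39 ± 0.29 (SE). Gfap, the filament of astrocytes and Müller glia, rose from the floor to 10188 ± 7423 (SD, n = 3), the cartilage collagen Col10a1 from the floor by 5.38 ± 0.39 (log2, SE), and the photoreceptor genes Rbp3, Nr2e3 and Sag by 5.85 ± 1.18, 5.29 ± 1.19 and 5.20 ± 1.28. The largest falls were those of the epithelial keratins Krt5 (-5.04 ± 1.17) and Krt15 (-4.92 ± 1.22), the transcription factor Osr2 (-4.97 ± 0.41), the contractile genes Tnnt2 (-4.76 ± 0.45) and Actc1 (-4.62 ± 0.77), the growth regulator Hmga2 (-4.56 ± 0.20), the embryonic globin Hbb-y (-4.34 ± 0.55) and the muscle regulator Myog (-4.23 ± 0.57).

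In WT 34 of 34 cell cycle genes fell with age (median -1.57), such as Uhrf1 (-2.33 ± 0.28, SE) and Cdc6 (-2.17 ± 0.20, SE). Among RPE functions, 16 of 29 transport, phagocytosis and polarity genes rose and 3 fell, led by Slc16a8 (3.73 ± 0.36, SE) and the potassium channel Kcnj13 (2.72 ± 0.39, SE). Of 15 visual cycle genes 7 rose and 2 fell, with Rdh5 at 4.16 ± 0.38 (SE) and the retinoic acid enzyme Aldh1a3 at -2.92 ± 0.45 (SE). Of 18 melanosome genes 7 rose, including Tyrp1 (2.13 ± 0.43, SE) and Dct (2.11 ± 0.30, SE), and none fell. Of 13 RPE transcription factors 2 rose, Otx2 (2.36 ± 0.45, SE) and Tbx2 (1.59 ± 0.22, SE), and 4 fell, led by Otx1 (-2.73 ± 0.60, SE). Adjusted over the list alone the counts were 34 falls for the cell cycle, 20 rises and 3 falls for transport, 9 and 2 for the visual cycle, 7 rises for the melanosome and 3 rises and 4 falls for the transcription factors. Other tissues moved at the same time: 20 of 22 endothelial markers rose, such as Cldn5 (2.92 ± 0.23, SE), 10 of 11 glial markers and 12 of 25 photoreceptor markers rose, and 7 of 9 erythroid markers fell. Adjusted over the list alone, 20 endothelial, 11 glial and 12 photoreceptor markers rose and 8 erythroid markers fell.

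Of 35 Wnt genes 3 rose and 19 fell, led by Wnt4 (-3.85 ± 0.25, SE) and Wnt6 (-3.84 ± 0.21, SE), and of 29 angiogenic and angiostatic factors 11 rose, such as Angpt2, and 5 fell, such as Sema3a. Among 27 TGF-beta and BMP genes 8 rose and 6 fell, among 27 basement membrane and elastic matrix genes 5 rose and 4 fell, among 14 other Sox genes 6 rose and 2 fell, and among 16 SOX9-dependent cartilage genes 7 rose, led by Col9a3 (3.49 ± 0.31, SE), and 2 fell. Of 24 lysosome genes 12 rose, including Ctsd (1.29 ± 0.25, SE), and of 18 interferon response genes 11 rose, including Bst2 (2.03 ± 0.34, SE). Of 21 cholesterol synthesis genes 12 fell, led by Acat2 (-1.48 ± 0.15, SE). For the remaining lists of cell state, 1 rose and 4 fell of 15 cyclin-dependent kinase inhibitors and p53 targets, 5 rose and 3 fell of 23 hypoxia and glycolysis genes, 1 rose of 27 oxidative phosphorylation genes and 7 rose of 18 immediate early and heat shock genes. Of other tissues, 3 rose and 5 fell of 16 retinal progenitor markers, 1 fell of 22 retinal neuron markers, 3 rose and 6 fell of 24 pericyte, smooth muscle and mesenchyme markers, 4 rose and 1 fell of 10 neural crest melanocyte markers, 2 rose of 17 macrophage markers, 2 rose and 5 fell of 16 skeletal muscle markers and 2 rose and 1 fell of 12 ciliary body and iris markers. Adjusted over the list alone, the counts changed by at most 2 in each of these lists.

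By camera 12 lists were called higher and 4 lower with age in WT. The 4 lower lists were the cell cycle (adjusted p = 1.68e-14), erythroid, Wnt and cholesterol lists, and the 12 higher ones included the endothelial (adjusted p = 4.41e-11), glial and photoreceptor lists. None was called with an estimated correlation, the cell cycle having an adjusted p = 0.432 with an estimated correlation and the glial list the lowest, an adjusted p = 0.316 with an estimated correlation. Median, mean and test had 1 sign in all called lists. They differed in sign in lists not called, such as hypoxia and glycolysis (median -0.09, mean 0.22) and retinal progenitors (median 0.54, mean -0.03). By fry, age in WT was called for lists such as glia (adjusted p = 2.58e-05 by fry), cell cycle (0.000432) and endothelium (0.00141). Other lists did not pass by fry, such as the photoreceptor list (adjusted p = 0.0825 by fry).

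In cKO, Ttr rose from 94.8 ± 13.2 to 60978 ± 21046 (SD, n = 3), a log2 fold change of 9.26 ± 0.29 (SE) with an adjusted p of 4.12e-08 by limma, Slc16a8 by 6.00 ± 0.36 and the organic anion transporter Slc22a8 from the floor by 5.78 ± 0.43. Gfap, Rbp3 and Sag were again among the 8 largest rises, with the myosin Myh1 (5.59 ± 0.55, SE), and Krt5, Krt15, Osr2, Hmga2, Tnnt2 and Hbb-y among the 8 largest falls, with desmoplakin (Dsp, -4.73 ± 0.58, SE) and Pitx1 (-4.13 ± 0.14, SE). All 34 cell cycle genes fell (median -1.52). Of the RPE lists, 19 of 29 transport genes rose and 2 fell, 8 of 15 visual cycle genes rose and 2 fell, 10 of 18 melanosome genes rose, and 5 of 13 RPE transcription factors rose and 2 fell. Rgr rose by 1.62 ± 0.32 (log2, SE) and Rpe65 stayed at the floor in all 6 cKO libraries. Of the lens markers 15 of 17 rose in cKO (median 2.996) and 1 of 17 in WT (median 1.03), and the interaction test of that list was called at the preset (median 1.72, adjusted p = 1.3e-08 by camera), with an adjusted p = 0.503 with an estimated correlation. Endothelial (16 of 22), glial (10 of 11) and photoreceptor (12 of 25) markers rose and 8 of 9 erythroid markers fell. Adjusted over the list alone, 19 transport genes rose and 3 fell, 9 visual cycle genes rose and 2 fell, and 11 melanosome, 16 lens and 17 endothelial genes rose. By camera 14 lists were called higher and 4 lower, with a lowest adjusted p = 0.492 with an estimated correlation. Fry called lists such as glia (adjusted p = 5.74e-05 by fry) and cell cycle (0.000523) in cKO, but not others, such as photoreceptors (0.0748).

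**Figure D4:**
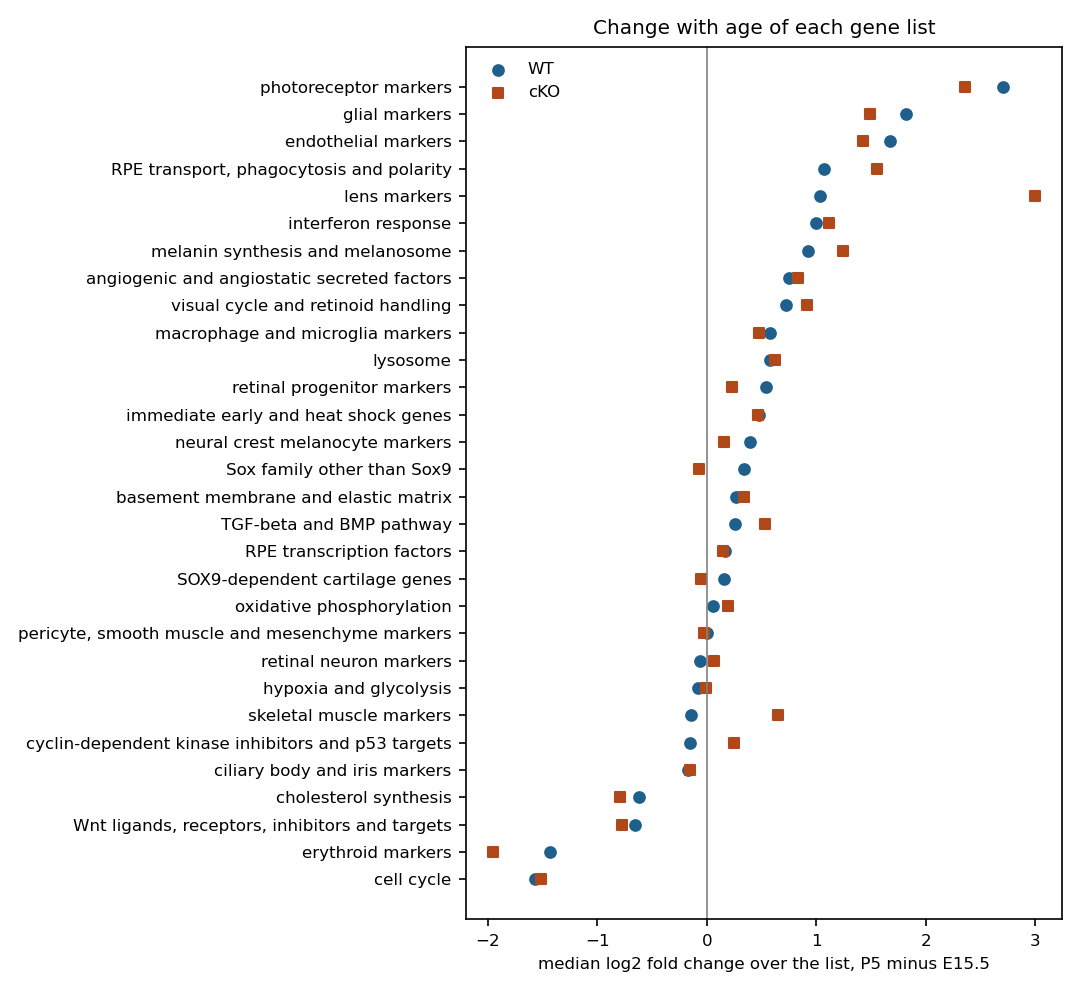
Median log2 fold change, P5 minus E15.5 (horizontal axis), of each of the 30 gene lists (vertical axis) in WT (circles) and cKO (squares). The cell cycle list lay at -1.57 and -1.52 and the photoreceptor list at 2.70 and 2.36 in WT and cKO.

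By limma, 2028 genes rose and 3143 fell with age in WT, 1089 and 1005 of them at least 2-fold, and 2379 rose and 3526 fell in cKO, 1263 and 1159 at least 2-fold. Rescaling by median ratios moved the age changes up by a median of 0.103 (log2) in WT and gave 2537 rises and 2438 falls in WT and 2880 and 2780 in cKO, so the split between rises and falls depends on the scaling. Library weights raised the count in WT from 5171 to 9606. The weight was 5.75 for P5 WT replicate 2 against 0.454 and 0.116 for replicates 1 and 3, so that count leans on replicate 2. Of the calls, 1679 rises and 2721 falls were shared by both genotypes, where 357 and 820 would be shared by independent lists. Across the tested genes, which are not independent replicates, the age changes in WT and cKO had a correlation of 0.93.

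The interaction asks whether the genotype effect differed between the ages, and it was called for 8 genes. The genotype effect on Rgr was lower at P5 than at E15.5 by a log2 difference of -6.02 ± 0.45 (SE, adjusted p = 0.000666 by limma), and that on Ttr was higher by 3.87 ± 0.41 (SE, adjusted p = 0.00544 by limma). Ism2 (2.07 ± 0.20, SE), Otogl (2.04 ± 0.26, SE), Kcnh1 (2.04 ± 0.26, SE) and the potassium channel Kcnk1 (1.74 ± 0.24, SE) had positive differences. Rgr and Otogl were at the floor in all 6 E15.5 libraries and Ism2 and Kcnh1 in 5 of 6, so no effect could be seen at that age and their differences restate the change at P5. That of Ttr rests on P5 values of which 3 of 6 were the same. The differences of Rpe65 (-2.84 ± 0.47, SE, adjusted p = 0.124), Sox9 (1.12 ± 0.24, SE, adjusted p = 0.435) and Slc16a8 (2.27 ± 0.50, SE, adjusted p = 0.538) did not pass over all genes and did adjusted over their lists alone. Of the lists, 6 were called higher and 5 lower at P5 than at E15.5 by camera, and none with an estimated correlation (lowest adjusted p = 0.216 with an estimated correlation). The count of genes was 7 positive and 1 negative, with 358 genes at an unadjusted p under 0.05, where 676 would be expected by chance. It fell to 2 among genes averaging at least 4 times the floor and rose to 32 with library weights. It ranged from 4 to 24 when 1 library was left out: 4 without any of E15.5 WT replicates 1, 2 and 3, E15.5 cKO replicate 1 or P5 cKO replicate 3, 5 without E15.5 cKO replicate 2, P5 WT replicate 2 or P5 cKO replicate 2, 16 without P5 WT replicate 3 and 24 without P5 cKO replicate 1.

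No gene was called for genotype at both ages, with 1 call at E15.5 and 33 at P5. Independent lists of these sizes would share 0.000444 falls, so the lack of overlap does not tell whether the effects differ between the ages. The genotype changes at E15.5 and P5 had a correlation of 0.07 across 13523 genes, which are not independent replicates. The genotype change and the WT age change share the WT libraries: at P5 their correlation was -0.04, and groups drawn with no genotype effect gave -0.58 to 0.25. With the WT libraries divided between both changes it turned to between 0.17 and 0.33.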

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

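Of the tests reported here, those with photoreceptor, glial, progenitor, lens and melanosome signal, of the fit of P5 libraries alone and of the Ttr signal were chosen after the data were seen, while the splits of the samples were not. The interaction test of the genotype effect, P5 minus E15.5, was called for Rgr (-6.02), Ttr (3.87), Ism2 (2.07), Otogl (2.04), Kcnh1 (2.04), Kcnk1 (1.74), Lypd1 (1.57) and Stxbp5l (1.49, named after its value was seen), as log2 differences. Rgr, Otogl and Stxbp5l were at the floor in all 6 E15.5 libraries and Ism2 and Kcnh1 in 5 of 6, so their values restate the change at P5. Of 100 labellings of the libraries within each age, the real one included, 14 called at least the real count of 8 genes, with up to 1635 in the others, so chance is not excluded for that count, and the largest counts point to a structure of the samples other than genotype. Median genotype effects differed between the ages, by camera at the preset, for the lists of lens (1.72), skeletal muscle (0.97), RPE transport (0.50), RPE transcription factors (0.32), TGF-beta and BMP (0.28), oxidative phosphorylation (0.12), SOX9-dependent cartilage genes (-0.19), cholesterol synthesis (-0.19), endothelium (-0.24), neural crest melanocytes (-0.24) and other Sox genes (-0.32), and with an estimated correlation for none.

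The Sox9 count was higher in P5 libraries labelled cKO, by 1.07 (95% limits 0.70 to 1.44). More glial RNA is argued against, since the upper 95% limit of the glial list's difference was 0.0861. More retinal progenitor RNA stays open. The upper 95% limit of the progenitor list's difference, the higher of both, was 0.544, but its spread is pooled with the E15.5 libraries. The P5 means of the progenitor list were 7.46, 8.05 and 9.35 in WT and 7.55, 8.23 and 8.09 in cKO. Its lower mean in cKO thus rests on WT replicate 3, and the limit does not decide. Of 11 glial and 16 progenitor genes tested, 2 and 3 stand in another list and 8 and 9 were above the floor in all libraries. A larger share of RPE stays open. With melanosome signal as a term Sox9 stayed at 1.07 ± 0.16 (SE, adjusted p = 0.0146, in a range of 0.00871 to 1 over all alternatives). But the mean of that list differed by -0.03 between the genotypes (95% limits -0.85 to 0.80), so the term could hardly move Sox9 and does not decide. More lens RNA stays open: with lens signal as a term the difference went from 1.07 ± 0.17 to 0.80 ± 0.19 (SE) and the call ended (adjusted p = 0.171) as the effect shrank and its error grew, and of 17 lens genes, none in another list and 3 above the floor in all libraries, the most abundant, Cryab, stood at 2836 ± 1212 (SD, n = 3) in WT and 3903 ± 825 in cKO. A transcript made from remaining exons, a response to the loss of SOX9 and a wrong label stay open as well, and gene-level values leave these untested.

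The 33 calls at P5 set Rgr and Rpe65 apart from 27 rises. Photoreceptor RNA carried over unequally is argued against as the only cause of these calls. In all 33 the genotypes did not overlap, while the photoreceptor means did (7.10, 8.18 and 10.96 in WT, 7.09, 10.14 and 9.18 in cKO). At nearly equal photoreceptor means, Rgr was 10706 in WT replicate 1 and 93.2 in cKO replicate 1. A share in the size of single changes stays open. All 33 were kept with photoreceptor signal as a term (25 genes tested, none in another list, 2 above the floor in all libraries, Rbp3 at 8868 ± 13210 in WT and 5565 ± 5157 in cKO, SD, n = 3). But the mean of that list differed by only 0.06 between the genotypes at P5 (95% limits -2.01 to 2.12). The term could thus hardly move a fold change, and its outcome does not decide the question. A lens term kept 13 calls. More lens RNA in cKO is argued against for Rgr and Rpe65 among them, whose log2 changes went to -6.51 and -3.50 with the term. For the other calls kept it stays open as a part of the change. The lens list mean itself differed by 1.49 between the genotypes (95% limits 0.29 to 2.70), so a call kept does not exclude such a part. More lens RNA also stays open for the 20 lost, whose median absolute log2 change went from 1.41 to 1.17 and median SE from 0.22 to 0.25. A spread pooled with the less variable E15.5 libraries stays open for the 2 calls kept in the P5 libraries alone, Lypd1 and Stxbp5l, which the floor leaves without spread in WT, and for the 31 lost. The log2 changes of these 31 were the same in both fits and their unadjusted p was at most 0.00588 in the P5 libraries alone, but the calls ended over all genes as the degrees of freedom went from 10.6 to 5.21 and the median SE from 0.217 to 0.253 (0.32 to 0.43 for Rgr, at -6.02). The SE was larger in the P5 libraries alone for 30 of the 31, so pooling lowered the error of these. The median SD within groups of the 33 calls was 0.115 at E15.5 and 0.325 at P5, and 8 of them, at the floor throughout E15.5, had no spread there. The 10 splits of 3 against 3 are too few for a share under 0.05: 4 gave at least the real count of 33 and the highest other gave 3716. That split set P5 WT replicates 1 and 2 and cKO replicate 1 against the others. Their photoreceptor list means were 7.10, 8.18 and 7.09, against 10.96 in WT replicate 3 and 10.14 and 9.18 in cKO replicates 2 and 3. The count thus points to a structure of the P5 samples other than genotype, which runs with photoreceptor signal. The deletion of Sox9 stays open as an untested biological explanation.

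Ttr was lower in E15.5 libraries labelled cKO, by -3.99 (95% limits -4.62 to -3.35). A lower share of RPE in these libraries is argued against, since the lower 95% limit of the melanosome list difference was -0.956 (18 genes, none in another list, 17 above the floor in all libraries, Dct at 6260 ± 1234 in WT and 5142 ± 977 in cKO, SD, n = 3). The 10 splits are too few for a share under 0.05, with 1 split reaching the real count of 1 call and 0 as the highest other. The deletion of Sox9 stays open as an untested biological explanation, as does a difference in tissue other than RPE that makes Ttr, where the ciliary body and iris list differed by 0.01 (95% limits -0.48 to 0.49) but 5 of its 12 genes stand in another list. For age the 10 splits are likewise too few, with 1 split reaching 5171 calls in WT (highest other 0) and 1 reaching 5905 in cKO (highest other 1).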

How the results depend on the processing

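The terms for marker signal and the omission of the pair of P5 libraries of lowest photoreceptor signal were chosen after seeing the data. The count of 33 at P5 became 19 above the floor in at least 6 libraries and 4 at 4 times the floor (fewer genes tested), 59 with library weights, 13 with the replicate number as a block, 206 with a photoreceptor and 225 with a melanosome term, 26 with a muscle term (21 of the 33 kept), 100 without that pair, 2 in the 6 libraries alone (fewer samples) and 12 to 132 with 1 library left out. The 1 call at E15.5 became 14 with library weights, 0 with the block and 1 to 4 with 1 library left out. The 8 interactions became 2 at 4 times the floor, 32 with library weights, 1 with the block and 4 to 24 with 1 library left out. The age count in WT rose from 5171 to 9606 with library weights. These weights were 0.454, 5.75 and 0.116 for P5 WT replicates 1, 2 and 3 and 0.319, 0.586 and 0.0441 for P5 cKO replicates 1, 2 and 3. Weighted results that involve P5 WT thus lean on its replicate 2. Sox9 at P5 kept its direction in all alternatives but lost its call at 4 times the floor, with the block and in the 6 libraries alone (1.07 each), with library weights (0.68) and with a lens term (0.80), and lay at 0.93 to 1.25 with 1 library left out. Sox9 at E15.5 lay at -0.13 to 0.023 with 1 library left out, turning positive without E15.5 WT replicate 1. The overlap of genotype calls became 1, a fall, at an unadjusted p under 0.01, where more genes enter. Independent lists would share 0.131 falls there (p = 0.123 by Fisher's exact test). With the WT libraries split between both changes, the correlation of the genotype change with the WT age change lay between -0.12 and 0.031 at E15.5, around the unsplit 0.03, and turned from -0.04 to between 0.17 and 0.33 at P5. Where no construction is named, the cause was not tested. For single genes, 264 values at P5 kept their call and 73 lost it, 17 and 1 at E15.5, 102 and 32 for the interaction and 288 and 0 for each age comparison. For lists 8 and 4 at E15.5 and 56 and 28 at P5 did, and of the 12 lists called at P5, RPE transcription factors, RPE transport, other Sox genes and TGF-beta and BMP lost their call without P5 WT replicate 3, the only library left out for lists, also chosen after seeing the data. Kept in all alternatives that tested them were Lypd1 of 16 named P5 genes (not tested at 4 times the floor), Rgr of 6 named interactions and all 16 named genes of each age comparison. The interaction has no fit of 6 libraries alone, the alternative that ended the call of Rgr at P5. The labels do not say whether replicate numbers pair the libraries. Same-number correlations between WT and cKO were -0.02, 0.27 and -0.02 at E15.5 and 0.78, -0.30 and 0.19 at P5. The best other number gave 0.22, -0.05 and 0.06 at E15.5 and -0.37, 0.19 and 0.71 at P5. These values show no pairing throughout and do not exclude one.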

Other observations

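Many of the genes called at P5 had low values. Of the 33 genes called, 8 were at the floor in all 6 E15.5 libraries, where 1.35 would be expected from the 553 such genes among those tested, and 20 averaged less than 4 times the floor. The potassium channel Kcnk1 rose from 174 ± 19.8 to 551 ± 101 (SD, n = 3) in cKO at P5.

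Of the tests of a delayed maturation of the RPE in cKO, the count of genes was chosen after the result was seen and the correlation was planned. If maturation were delayed, genotype changes at E15.5 might run against the age change in WT. Across genes, which are not independent replicates, their correlation was 0.0283, where libraries drawn without a genotype effect gave a mean of 0.079 (95% range -0.15 to 0.28). Of the 75 RPE list genes tested, 32 rose with age in WT, and 21 of these were lower in cKO at E15.5, against a median of 12 (95% range 1 to 26) in 100 simulations. Both values lay within the simulated ranges, and the hypothesis stays open.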
